A study of Homo sapiens with 1 sample.

How the data were processed

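The sample was the DNA-binding region of human EGR1 (residues 334 to 423) with a GST tag and an Alexa647 label, per the labels, measured on 1 array. No samples were grouped, and no values of other samples were used (0 columns). The deposited per-spot table gives intensity: the raw median brightness, the local scanner background, the difference between them, the mean brightness, and the percent of saturated pixels per the file headers. Its main column is a normalised intensity that the authors derived from the raw median. Dividing the raw value by the median of the experimental spots in the 7 by 7 window around it, and multiplying by the median of all experimental spots (8495), returned this column for 100% of spots within 1 unit. The deposited series matrix holds the same intensity (largest difference 0). The array had 20250 spots, of which 1124 were control spots without a normalised value and 19126 were used.

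Probe names gave the modified bases, and duplex sequences were read from the hairpin probes. The names numbered 1107, with 10 to 18 spots each. Spots with the same sequence and modifications were combined, since 141 of 959 sequences had more than 1 name. The mean log2 intensity of such names ranged over a median of 0.06 and at most 0.24. Log2 intensity was used without an offset and averaged over spots. The single array and the number of spots limit the precision. The raw scale ends at 65535, which 80 spots reached, and 952 spots had saturated pixels. Among EGR1-site spots, 7.1% had saturated pixels in the dimmer part of the slide and 30.2% in the brighter part. The raw value was at or below the local scanner background in 70.9% of spots, and no background was subtracted in the main comparisons. Where local background was subtracted as an alternative, these spots were left out, and 127 sequences lost all their spots.

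The following choices were made before the data were examined unless stated. Reference sites were compared with unmodified random controls by the difference of medians and a two-sided exact permutation test on sequence means. Because there were 37 such controls, fewer than the 50 set for using a percentile, a sequence was called bound when its mean exceeded the highest control. The plan held the permutation test only for larger sets than the reference sites, so its use there was a departure. Pairs of sequences were compared over their spots with limma (version 3.58.1, R 4.3.3; lmFit and eBayes with trend), separately for each family. Families were substitutions, 5mC outside CpG, 5mC in CpG, states of the native CpGs, hemi-methylated strands, 5mC in random controls, and 5mC against T, all but the controls built on the bound EGR1 site. The plan named 5mC in the flank of a site in place of the random controls. These were used instead because no such probes were found. Adjusted p-values are Benjamini-Hochberg values within a family, and a change was counted at an adjusted p under 0.05 and at least 1.5-fold. Extremely small values arise from many spots of 1 array. Full methylation was compared with the sum of the hemi-methylated effects by a limma interaction. The correlation of T with 5mC used permutation p-values (100000 resamples). Families with 5hmC, direct comparisons between bases and between CpGs of mixed modification (two-sided permutation tests on spots) and comparisons between CpG and other contexts were added after the data were examined. Other steps used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.

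Sequences named in the text were chosen by a rule set beforehand: the EGR1 site and its positions, the 5 largest decreases and increases per family past the adjusted p, the 10 largest past the fold minimum as well, each methylation state of the native CpGs, and the 10 brightest bound sequences of other factors. Further substitutions at positions 3, 5, 6 and 9, the C3 pairs beside G4T, and control sequences named outside this rule were chosen after their values were seen. Lists of motifs for other factor classes were also set beforehand.

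Alternatives set beforehand were raw intensity, the spot minus local scanner background, subtraction of the control median (7560, with a floor of 1275), an offset at the 5th percentile (6159), the median over spots, removal of spots beyond 3 scaled median absolute deviations (974 spots), a 15 by 15 window, both sets of alternate spots, a permutation test per pair, no fold minimum, a minimum of 2-fold, the 95th and 99th percentiles of controls, and inclusion of all 4 reference sites. Alternatives chosen after seeing the data were a window without EGR1-site spots, removal of spots with saturated pixels, the dim part of the slide, 1 probe name per sequence, and other fold minima for the added families, the native CpG states, the hemi-methylated strands, 5mC in random controls and 5mC against T. For 5hmC in CpG, inclusion of all 4 reference sites was also chosen then. The limma step was tested on simulated data with 18 against 54 spots in 400 pairs. Of pairs simulated at a log2 change of -0.30, 82% were found at an adjusted p under 0.05, as were 100% at -1.00 and 2% without a change. The permutation test was run on its own simulated pairs, with spreads drawn from all sequences. It found 100% of 200 pairs changed by -0.585 and 1.5% of 200 unchanged pairs. At -0.585 the limma step also found 100%.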

Results

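The DNA-binding region of human EGR1 (residues 334 to 423), a zinc-finger transcription factor also called ZIF268, was measured on 1 protein-DNA array. The EGR1 gene (gene identifier 1958) lies on chromosome 5 at 138465479 to 138469303 of the human reference assembly. On such an array, surface-bound DNA hairpins present a duplex site, and the fluorescence of a spot reports how much labelled protein the site retained. The signal came from 19126 spots holding 959 sequences. Of these sequences, 218 were built on the EGR1 site, 228 on a HOXB13 site and 223 on a RUNX1 site, and 99 were random or other controls. The rest, built on 1 further reference site, are not described here and enter only pooled values. The sequences held C, 5-methylcytosine (5mC) or 5-hydroxymethylcytosine (5hmC), as read from the probe names. There was 1 sample and no replicate array. Errors and p-values therefore measure only the spread between spots of 1 slide, and pairs built on the same site share their reference spots. The SD of log2 intensity over the spots of a sequence had a median of 0.25.

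The first comparison asked which sites the protein bound above random DNA. EGR1 gave a strong signal on its own site and none above the controls on the HOXB13 and RUNX1 reference sites. The EGR1 site AGCGTGGGCGT had a normalised intensity of 37062 ± 9681 (SD, n = 54 spots). The HOXB13 site GTTTTATTGGG gave 7875 ± 1358 (SD, n = 18 spots). The RUNX1 site TGTTGCGGTTG gave 8657 ± 1498 (SD, n = 36 spots). The 37 unmodified random controls had a median of 7397 and ranged from 6162 to 16103. The EGR1 site lay 4.89-fold above the control median and 2.27-fold above the highest control, AAACAGGGGGG. With 1 of 4 sites bound, the median of the sites exceeded that of the controls by 0.15 (log2, two-sided exact permutation p = 0.145 over 101270 splits). That median does not change with the brightness of the highest site, so the test cannot judge binding to the EGR1 site. A sequence counted as bound when its mean log2 intensity exceeded the highest control. Of the EGR1-site sequences, 119 of 218 did so. This level rests on 1 G-rich control, the next highest being CGCCAGGCTCA at 9830, so sequences called not bound can lie above every other control. At the 95th percentile of controls, 182 EGR1-site sequences were above.

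Some sequences built on the other sites were also bound. They numbered 10 of 642 and came from 3 base sequences. A HOXB13 site with T7C and T8G, GTTTTACGGGG, reached 29285 ± 9587 (SD, n = 18 spots), 3.59-fold over its own reference site. HOXB13 T8G alone, GTTTTATGGGG, reached 22942 ± 4865 (SD, n = 18 spots), 2.91-fold over that reference. The RUNX1 site with T10G, TGTTGCGGTGG, reached 19528 ± 2965 (SD, n = 18 spots), 2.26-fold over its reference. Positions in these tokens count from 1 at the 5′ end of the printed strand. The other 7 carried 5mC, 5hmC or both in the HOXB13 sequences and ranged from 18656 to 26476. Motifs of other factor classes, listed before the data were examined and searched in the unmodified duplexes with their flanks, gave few bound sequences. All 9 EGR-type sequences were bound, with a median of 36293, and all were built on the EGR1 site. None of 3 ZFP57 and 1 homeobox sequences was bound. Bound sequences numbered 2 of 50 with a MYB motif, 1 of 2 with an E-box and 1 of 6 with a p53 motif. The 2 with a MYB motif were the unmodified HOXB13 sequences above, where the motif spans flank and site. Both E-box sequences and 2 of the p53 ones were built on the EGR1 site. No sequence held a motif of the SP and KLF, CRE and AP-1, NRF1, Kaiso, nuclear receptor, C/EBP, E2F, YY1 or CTCF lists, and 1 further list is not described here.

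**Figure D1:**
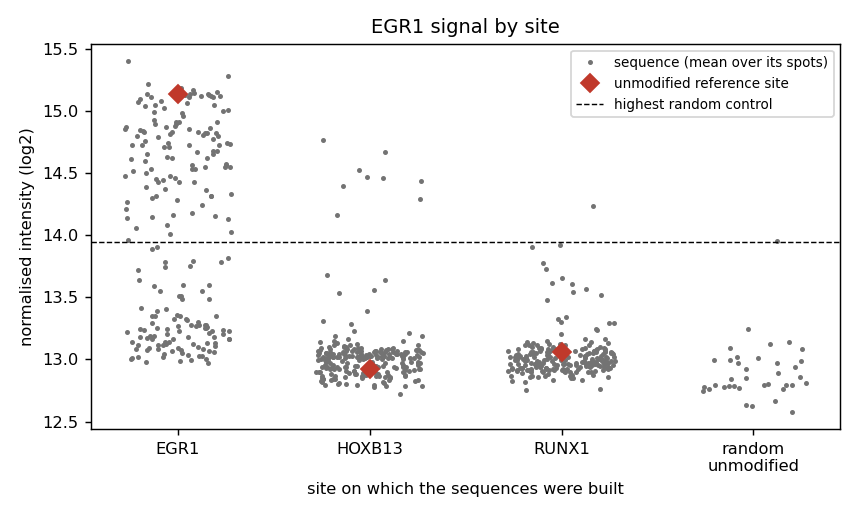
Mean log2 normalised intensity of each sequence (points, over its spots) by the site on which it was built, with the unmodified reference sites (diamonds) and the highest of 37 random controls (dashed line). Of the reference sites shown, that of EGR1 lay above the line, as did 9 sequences built on the HOXB13 site and 1 on the RUNX1 site.

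Single-base substitutions asked which bases of the EGR1 site the signal depended on. The G bases at positions 4, 7 and 8 mattered most, and the first and last bases least. Positions count from 1 at the 5′ end of the G-rich strand of the site, whose GCGTGGGCG core runs from position 2 to 10. Of 33 substitutions, 15 lowered the signal at least 1.5-fold at an adjusted p under 0.05 (limma), and 0 raised it. No substitution raised the signal even at an unadjusted p under 0.05 (0 of 33), and 28 lowered it when no fold minimum was set. Saturated pixels among the brightest spots could hide a small rise. G8C fell by 1.88 on the log2 scale, to 9977 ± 2453 (SD, n = 36 spots), a 3.69-fold decrease (SE 0.071, adjusted p = 5.3e-135). G4C fell by 1.88, to 9945 ± 1906 (SD, n = 54 spots; SE 0.064, adjusted p = 1.1e-164). The log2 changes of G7A, G7T and G7C were -1.81, -1.79 and -1.79. All 9 substitutions at positions 4, 7 and 8 left the site at or below the highest random control, so background limits the folds given for them.

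Other positions tolerated some bases and not others. At position 6, G6C fell by 1.38 to 14279 ± 3475 (SD, n = 36 spots), G6T fell by 0.85, and G6A fell by 0.34. At position 5, T5A fell by 0.97 and T5C fell by 0.74, whereas T5G, which makes the core GCGGGGGCG, fell by 0.24 to 31504 ± 7906 (SD, n = 18 spots, adjusted p = 0.013). The cytosines of the native CpGs were less sensitive, with a median change of -0.39 at position 3 and -0.38 at position 9. At those cytosines the largest decreases came with G (C3G -0.58, C9G -0.65) and the smallest with T (C3T -0.26, C9T -0.23). Only 5 substitutions did not pass the adjusted p, namely the 3 at position 1, T11A and T11G.

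**Figure D2:**
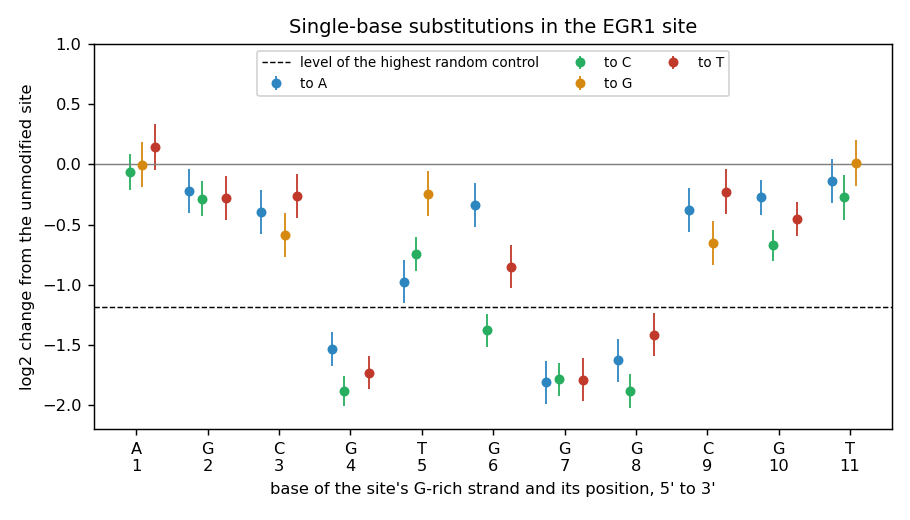
Change in log2 normalised intensity (y axis) for each base substitution at each position of the EGR1 site (x axis), with bars of the 95% confidence interval and the level of the highest random control (dashed line). Substitutions at positions 4, 7 and 8 lie below the line and those at position 1 near 0.

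Methylation outside CpG was compared by setting 5mC against C at the same base of an otherwise identical sequence. In the native site, 5mC opposite G8 on the C-rich strand, a CpC context, lowered the signal, and 5mC opposite the other non-CpG bases did not detectably do so. Opposite G8, the signal fell by 0.47 (SE 0.092), to 26260 ± 3736 (SD, n = 18 spots), a 1.38-fold decrease (adjusted p = 3.0e-05). The changes opposite G2, G6 and G7 were -0.01, -0.01 and -0.07 (adjusted p = 0.983, 0.983 and 0.791). Set directly against 5mC opposite G7, 5mC opposite G8 was lower by a log2 difference of -0.40 (SE 0.079, two-sided permutation p = 3e-05, adjusted 5e-05 over 5 such comparisons). The decrease opposite G8 no longer passed the test when spots with saturated pixels were left out (-0.30, adjusted p = 0.057), in 1 set of alternate spots (-0.38, adjusted p = 0.11) or on raw intensity (-0.42, adjusted p = 0.19). Leaving out saturated spots removes the brightest spots of the brighter partner, which narrows a decrease. In the dim part of the slide, with fewer saturated spots, the decrease passed (-0.44, adjusted p = 0.048).

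Over all 38 non-CpG pairs, 0 were lower and 0 higher at the 1.5-fold minimum (limma), with 9 at an unadjusted p under 0.05. Without the fold minimum, 6 were lower and 1 higher. At C9, 5mC lowered the signal with G10T, by -0.35 (adjusted p = 0.0013), and with G10A, by -0.33 (adjusted p = 0.0029), but not detectably with G10C (-0.15, adjusted p = 0.233). The cytosine that G2C creates fell by 0.29 with 5mC (adjusted p = 0.0029), and the cytosine that G10C creates rose by 0.17 (adjusted p = 0.030). The remaining decreases were at C3 with G4A (-0.24, adjusted p = 0.011) and with G4T (-0.23, adjusted p = 0.020), where the unmethylated partner was not bound. In 18 of the 38 pairs the partner was not bound, which leaves little signal to lose.

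Methylation within CpG was compared in the same way for the G-rich strand, the C-rich strand and both strands. The only changes past 1.5-fold were gains in a substituted site that was not itself bound. In the G6C sequence, whose change creates a CpG and lowers the signal below the highest control, 5mC on the G-rich strand raised the signal from 14279 to 22382 ± 3939 (SD, n = 36 spots), a log2 change of 0.67 (SE 0.077, 1.59-fold, adjusted p = 1.9e-13). Methylation of both strands raised it to 23009 ± 5164 (SD, n = 18 spots), a log2 change of 0.70 (SE 0.099, 1.62-fold, adjusted p = 1.9e-09). Measured from such a low partner, the gain depended on background. The change on the G-rich strand was 1.31 with the control median subtracted and 2.03 with local background subtracted, the latter only over spots above that background. The G6C pairs were the only 2 of 32 CpG pairs past both thresholds, and 0 were lower at 1.5-fold (limma, with 5 lower at an unadjusted p under 0.05). Without the fold minimum, 4 were lower and 3 higher, among them T5C with 5mC on the G-rich strand (-0.26, adjusted p = 0.0073), the CpG of G2C and C3G methylated on both strands (-0.30, adjusted p = 0.019) and A1C methylated on both strands (0.33, adjusted p = 0.018). The A1C gain no longer passed in 1 set of alternate spots (0.21, adjusted p = 0.51), with saturated spots left out (0.30, adjusted p = 0.55), with a wider window (0.31, adjusted p = 0.062) or with 1 probe name per sequence (0.37, adjusted p = 0.058). In the dim part of the slide it was 0.47 (adjusted p = 0.043). In 12 of the 32 CpG pairs the partner was not bound, which leaves little signal to lose.

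The strand that carried the methyl group made a difference at some CpGs. None of the 11 pairs with 5mC on the C-rich strand alone passed the adjusted p (limma, 0 of 11 in either direction). Only 7 of these pairs had a bound unmethylated partner. Comparing the G-rich with the C-rich hemi-methylated state directly, G6C was higher by 0.47 (adjusted p = 2.8e-05) and T5C lower by a log2 change of -0.42 (adjusted p = 8.6e-05). The CpGs at positions 4 and 3 gave -0.21 and -0.20 (adjusted p = 0.039 and 0.045). Neither sequence compared at position 4 was bound, and at position 3 the difference vanished on raw intensity (0.00049). No strand difference reached 1.5-fold (limma, 0 of 10, with 4 at an unadjusted p under 0.05). Methylation of both strands did not detectably differ from the sum of the hemi-methylated effects at any of 10 CpGs (limma interaction, -0.18 to 0.16, lowest unadjusted p = 0.194, all adjusted p = 0.935). At positions 4, 6, 7 and 8 the unmethylated sequence was not bound, which leaves little signal to compare.

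The native site has CpGs at positions 3 and 9, and each was measured in each methylation state. Methylating C3 lowered the signal slightly, and methylating C9 did not detectably change it. With 5mC at C3 on the G-rich strand the signal was 31194 ± 7175 (SD, n = 36 spots), a log2 change of -0.24 (SE 0.074, adjusted p = 0.0045). With both strands methylated at this CpG it was 29593 ± 4818 (SD, n = 18 spots), a change of -0.30 (SE 0.094, adjusted p = 0.0045). The corresponding values at C9 were 35224 ± 6788 (SD, n = 36 spots; -0.06, adjusted p = 0.681) and 34659 ± 7580 (SD, n = 18 spots; -0.09, adjusted p = 0.671). On the C-rich strand, 5mC opposite G4 gave -0.04 (adjusted p = 0.713; -0.36 and 0.039 on raw intensity, -0.41 and 0.042 with local background subtracted) and opposite G10 gave -0.02 (adjusted p = 0.807). None of the 6 states reached 1.5-fold (limma, 0 of 6, with 2 at an unadjusted p under 0.05). Set directly against each other, 5mC at C9 was higher than 5mC at C3 by 0.18 (SE 0.070, two-sided permutation p = 0.0093, adjusted 0.012, 36 against 36 spots), and the fully methylated states differed by 0.21 (SE 0.099, permutation p = 0.041). The decrease at C3 on the G-rich strand no longer passed in 1 set of alternate spots (-0.14, adjusted p = 0.58), with saturated spots left out (-0.14, adjusted p = 0.58) or with 1 probe name per sequence (-0.17, adjusted p = 0.39). The fully methylated state at C3 also failed under these settings and on raw intensity (-0.30, adjusted p = 0.20) and with local background subtracted (-0.30, adjusted p = 0.30). Leaving out saturated spots removes the brightest spots of the brighter unmodified site, which narrows a decrease. In the dim part of the slide, with fewer saturated spots, both decreases at C3 passed (-0.30 and -0.43, adjusted p = 0.025 each). Both native CpGs methylated at once were not analysed here.

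**Figure D3:**
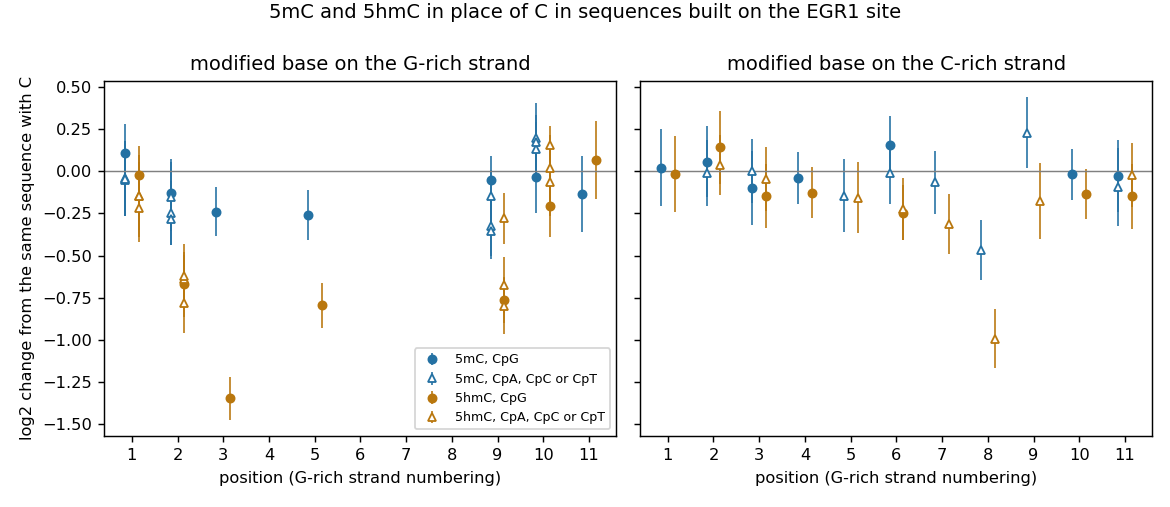
Change in log2 normalised intensity (y axis) with 5mC (blue) or 5hmC (orange) in place of C on 1 strand, by position (x axis) and context (CpG filled circles, other contexts open triangles), for pairs whose unmodified partner was bound, with bars of the 95% confidence interval. The 5hmC change at position 3 of the G-rich strand, -1.35, lies lowest, and 5mC and 5hmC opposite position 8 lie at -0.47 and -0.99.

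Methylation of random control sequences was compared in the same way. None of the unmethylated control sequences was bound, so there was little signal for 5mC to lower. These pairs therefore cannot show what 5mC does in a bound sequence. Over 30 pairs the median change was 0.01 and the range was -0.37 to 0.17. None passed the adjusted p (limma, 0 of 30, with 3 at an unadjusted p under 0.05).

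Thymine carries a methyl group at the same carbon as 5mC, so T and 5mC were compared at the same base. In all 22 comparisons the paired base differs as well, G opposite 5mC and A opposite T. At position 5 of the native site, where T is the native base, 5mC gave 18382 ± 4312 (SD, n = 36 spots) against 37062 with T, a log2 change of -1.01 (SE 0.071, adjusted p = 2.4e-28). The 5mC sequence is a methylated form of T5C, which without 5mC already gave 21882. At position 8 of the G-rich strand 5mC was also below T, by a log2 change of -0.58 (1.49-fold, adjusted p = 6.3e-11), although neither sequence was bound. At position 6 of the G-rich strand, 5mC and T gave 22382 and 20402 (log2 difference 0.14, adjusted p = 0.12), both above C at 14279. On the C-rich strand, 5mC exceeded T by 1.74 opposite position 7, 1.49 opposite position 4, 1.16 opposite position 8 and 0.59 opposite position 5. In these comparisons T is part of the substitutions G7A, G4A, G8A and T5A, so the other strand changes too, and the first 3 of these sequences were not bound. Over 22 bases, 5mC was at least 1.5-fold lower than T at 1 and higher at 4. The 22 bases are not independent replicates. Pooled over both strands, the changes from C to T and from C to 5mC were not detectably correlated. Pearson r was 0.38 (permutation p = 0.0891) and Spearman rho was 0.29 (permutation p = 0.187), with 2 coefficients computed. Without the 2 bases farthest from the median, r was 0.23. Because both changes share the same C, normalised intensities simulated without any effect gave a median rho of 0.42 and an upper limit of 0.745. Rank correlation was higher on raw intensity (rho 0.58, permutation p against 0 of 0.0061) and with local background subtracted, only over spots above it (rho 0.56, permutation p against 0 of 0.0087). That limit was not simulated on these scales. It also assumed no effects, whereas the measured changes from C to T ran from -1.81 to 0.74, so it cannot judge these correlations. On normalised intensity the covariance was 0.0565 against a median of 0.0031 in the simulation. There rho was 0.34 when the C spots were split so that none was shared, so the shared C is not shown to account for the rho of 0.29.

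**Figure D4:**
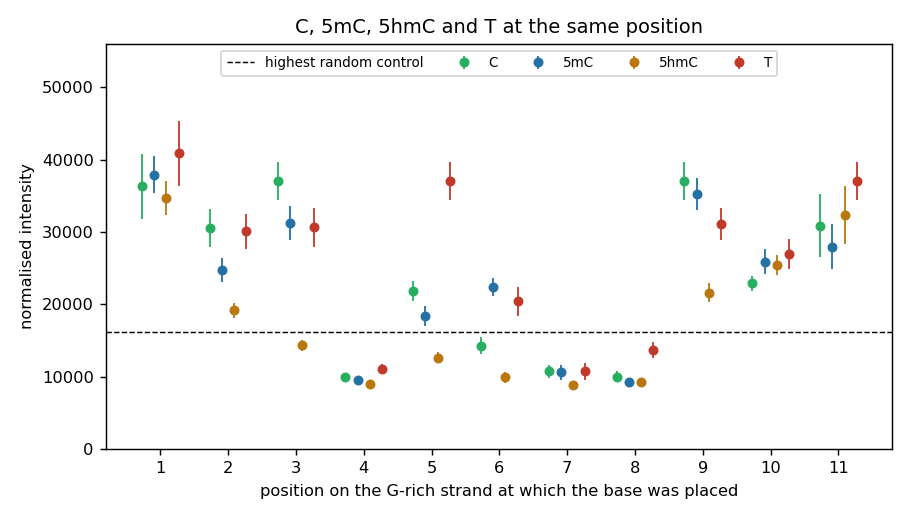
Normalised intensity (y axis) of sequences with C, 5mC, 5hmC or T at each position of the G-rich strand (x axis), with bars of the 95% confidence interval of the mean and the highest random control (dashed line). At position 3 the values are 37062 with C, 31194 with 5mC, 14323 with 5hmC and 30616 with T.

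The array also held 5hmC, and comparisons of 5hmC with C and with 5mC were added after the data were examined. This base lowered the signal more than 5mC at several bases, and its largest change from C was at C3. At C3 on the G-rich strand, 5hmC gave 14323 ± 2249 (SD, n = 36 spots), a log2 change of -1.35 (SE 0.064, 2.54-fold lower, adjusted p = 1.3e-43), which is below the highest random control, so background limits this fold and the differences taken from it. At C9 it gave 21570 ± 4024 (SD, n = 36 spots), a change of -0.76 (SE 0.068, 1.70-fold lower, adjusted p = 2.8e-20). With both strands modified, the changes at the same CpGs were -1.39 and -0.89. The signal with 5hmC at C9 exceeded that with 5hmC at C3 by 0.58 (SE 0.059, permutation p = 1e-05, the smallest the permutations can give). Opposite G8 on the C-rich strand, 5hmC gave 18398 ± 3681 (SD, n = 18 spots), a change of -0.99 (SE 0.089, 1.99-fold lower, adjusted p = 6.4e-19). On the C-rich strand of the native CpGs, 5hmC did not detectably change the signal, with -0.13 opposite G4 and -0.14 opposite G10 (adjusted p = 0.158 and 0.113).

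Outside CpG, 5hmC lowered 6 of 38 pairs at least 1.5-fold, and within CpG it lowered 8 of 32. In both families 0 pairs rose at 1.5-fold (limma, with 1 non-CpG and 0 CpG pairs higher at an unadjusted p under 0.05). Besides the site opposite G8, the non-CpG decreases were at C9 with G10A (-0.80) and G10T (-0.67) and at the cytosine of G2C alone (-0.64), with C3A (-0.78) and with C3T (-0.62). The T5C sequence fell by 0.79 with 5hmC on the G-rich strand and by 0.97 with both strands modified. The 5hmC forms of T5C, and of G2C with C3A, were not bound, so background limits these values. Against 5mC at the same base, 5hmC was at least 1.5-fold lower in 8 of 70 pairs and higher in 0 (limma, with 0 higher at an unadjusted p under 0.05). The largest of these differences were in the G6C sequence, -1.36 with both strands modified and -1.19 on the G-rich strand. At C3 the difference was -1.11 and at C9 it was -0.71. The 5hmC sequences of G6C and C3 were not bound, so background limits these values and their order. In the random controls, 5hmC gave a median change of -0.08 over 30 pairs, of which 1 passed the adjusted p, CGCCAGGCTCA, with a change of -0.50 (adjusted p = 0.0080).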

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

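The tests of probe yield and of thymine, given with the other observations, were chosen only after the results were seen. A group of the array's own control spots, a run of T bases outside every comparison of the report, was brighter than random DNA. Over 17 spots, its median raw brightness was 1.82 times the median of the surrounding window. The highest random control had a median of 1.72 on this scale, the random controls as a whole had 0.89, and 1005 empty positions had 0.54. Another pair of control spot groups had medians of 1.63 and 1.57, below the highest random control, so brightness is not particular to this group. Its signal drew attention because it comes from data without a normalised value, and no explanation was tested.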

How the results depend on the processing

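Alternatives chosen after seeing the data were the window without EGR1-site spots, saturated spots left out, the dim part of the slide, 1 probe name per sequence, and other fold minima for families without a planned one. So was the inclusion of all 4 reference sites for 5hmC in CpG. Of 372 comparisons of main counts and values over 19 settings, 333 kept their size or side of the threshold. Removing the fold minimum admits smaller changes by construction. The lower counts were then 28 substitutions, 6 5mC pairs outside CpG (with 1 higher), 4 in CpG (with 3 higher) and 2 native states. With 5hmC they were 10 pairs outside CpG (with 1 higher), 16 in CpG and 22 against 5mC. Lower hemi-methylated pairs numbered 3 (with 1 higher) and those of 5mC against T 5 (with 6 higher). At 2-fold, stricter by construction, 0 CpG pairs were higher with 5mC, and lower counts with 5hmC were 0 outside CpG, 2 in CpG and 4 against 5mC. The 95th percentile of controls, a lower bar by construction, gave 47 sequences of other sites in place of 10. Including all 4 reference sites, which adds pairs, gave 3 substitutions higher, 1 5mC pair outside CpG and 2 in CpG lower, and 15 5hmC CpG pairs lower. For the settings that follow, the cause was not tested. Subtracting the control median gave 3 lower 5mC pairs outside CpG, 15 lower 5hmC CpG pairs, 19 of 5hmC against 5mC, 2 lower and 1 higher hemi-methylated pairs, and 3 lower of 5mC against T. An offset gave 0 higher 5mC CpG pairs, 3 lower 5hmC pairs outside CpG and 5 in CpG. Leaving out outlier spots, taking even spots, or the median over spots each gave 2 lower of 5mC against T in place of 1. Subtracting local scanner background left out the 70.9% of spots at or below it. It gave 1 lower 5mC pair outside CpG, 15 of 5hmC against 5mC, 1 higher hemi-methylated pair and 17 sequences of other sites. Those 17 were judged against only 18 of the 37 random controls, the rest having no spot left. The correlation of T with 5mC rose on raw intensity (rho 0.58, permutation p against 0 of 0.0061) and with background subtracted (rho 0.56, 0.0087). The simulation without any effect used normalised intensity only, so its upper limit of 0.745 cannot judge these values. Of 810 comparisons of 61 named pairs, 694 kept direction and side of the threshold, 111 no longer passed, 2 newly passed and 3 reversed. The median over spots kept the p-values of the main comparison. Its 61 comparisons, all counted as kept, could therefore change direction but not side of the threshold. The reversed ones were the hemi-methylated difference at position 3 (0.00049 raw, 0.0013 background-subtracted) and 5mC against T at position 4 of the G-rich strand (0.14 background-subtracted). Raw intensity ended the most calls (22), then odd spots (17), background subtraction (16) and saturated spots left out (15). The dim part of the slide ended 9. Leaving out saturated spots removes the brightest spots of the brighter sequence, which narrows a difference. The gain with 5mC in the G6C sequence passed the adjusted p in each setting run. Signal over background limits the comparisons, since pairs whose partner lay at the control level have little signal to lose.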

Other observations

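The tests of probe yield and of thymine, the context comparisons and those of CpGs with mixed modifications were chosen only after the results were seen. In CpGs that carried 5hmC on 1 strand and 5mC on the other, the signal differed between the arrangements at 4 of 10 CpGs (two-sided permutation tests on spots, Benjamini-Hochberg adjusted). Both marks change strand between the arrangements, so a difference cannot be assigned to 5hmC alone. At the CpG of position 3, 5hmC on the G-rich strand gave a log2 change of -1.35 from the unmodified site (14457 ± 3069, SD, n = 18 spots, adjusted p = 1.5e-26), and 5hmC on the C-rich strand gave -0.31 (29393 ± 5251, SD, n = 18 spots, adjusted p = 0.0026). At position 9 the changes were -0.70 (adjusted p = 4.7e-11) and -0.17 (adjusted p = 0.129). The arrangements differed by -1.04 at position 3 (permutation p = 1e-05, the smallest the permutations can give, adjusted 5e-05) and by -0.53 at position 9 (permutation p = 3e-05, adjusted 0.0001). The others past the threshold were the CpG of G2C and C3G (-0.47) and that of G6C (-0.34). In G6C, whose unmodified form was not bound, 5hmC alone gave -0.52 on the G-rich strand and -0.55 on the C-rich strand. There 5mC alone gave 0.67 and 0.20. With 5hmC on the G-rich strand, the sequences at position 3, of G2C and C3G, and of G6C were not bound, nor was that of G6C with 5hmC on the C-rich strand, so background limits these values. Of 20 such pairs, 3 were at least 1.5-fold lower.

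The base after the modified cytosine was compared in 30 contexts per modification, of which 3 with 5mC and 12 with 5hmC differed from CpG past the threshold. In all but a pair of these, with 5hmC at positions 9 and 10, 1 or both of the unmodified sequences were not bound. At C9 each context was bound. The 5mC change differed from that in CpG by -0.27 in CpA (limma interaction, adjusted p = 0.131) and by -0.30 in CpT (adjusted p = 0.0824), neither past the threshold. The 5hmC change was less negative in CpC than in CpG, by 0.48 (adjusted p = 2.3e-05), and did not detectably differ in CpA (-0.04) or CpT (0.09). At position 10 it was higher in CpT than in CpG by 0.36 (adjusted p = 0.0021).

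The stronger decrease with 5hmC than with 5mC was set against technical explanations. A yield of 5hmC probes that is lower by 1 factor would change all of them alike, but the 95% intervals of 38.2% of those with a bound unmodified partner (13 of 34) excluded their median change of -0.17, 10 below it and 3 above. This argues against a common loss as the whole cause, and a yield that varies with position stays open. In the dim part of the slide 96.5% of the difference was left (-0.51 against -0.53, over 22 pairs), which decides nothing, because a scanner ceiling narrows the difference and cannot widen it. The design has 1 group, so no biological explanation was tested.

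The signal of sequences built on other sites was set against spot quality and chance similarity to the EGR1 core. All 10 bound sequences (100%) stayed above the highest control in both sets of alternate spots, which argues against a few bright spots. They also did so with a wider window. Neither check separates places on the slide, so an effect of place stays open. A score adding up the EGR1 substitution values ranked 174 unmodified sequences of these sites by signal (Spearman rho 0.46, permutation p = 1e-05, the smallest the permutations can give), and the 3 unmodified bound ones were at or above the 96.6th percentile of the score. A partial EGR1 core in the duplex may therefore explain part of this signal, as a hypothesis that rests on the value pooled over sites. The sequence with the highest score was not bound. The brightest unmodified sequence that was not bound, TGTTGCGCGTG on the RUNX1 site, scored below the middle of the 174. Taken by site, rho was 0.68 over 64 HOXB13-site sequences and 0.25 over 61 RUNX1-site ones. The sequences are close variants of a few sites, and many share a score. The permutations treated them as independent, so the p of 1e-05 can overstate the support for this hypothesis.

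The lower signal with 5mC at C3 than at C9 was set against the scanner ceiling and against the effect of T. In the dim part of the slide the change at C9 exceeded that at C3 by 0.27 (SE 0.165), too imprecise to say whether the ceiling hid a decrease at C9. 5mC and T differed by 0.02 (SE 0.091) at C3 and 0.17 (SE 0.086) at C9, at most 1.97 standard errors, so equal effects of 5mC and T stay open. The paired base differed as well, G with 5mC and A with T, so these values do not isolate the base itself. No biological explanation was tested.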
